A study of Drosophila melanogaster with 9 samples.

How the data were processed

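Testes were dissected by hand and small RNA libraries were made with a TruSeq kit, per the labels' protocols. The submitters' processing notes name Bowtie version 1 and DESeq2 without their role. The aligner settings, the genome build, the read lengths kept in the stage tables and the handling of reads that map to several elements are not given in the sources used here. For the bam, bgcn, can, sa and y w libraries, the deposited tables hold raw read counts per transposon and per piRNA cluster and a normalised signal for each. That signal equals the raw count times 1 factor per library, the same in both tables of a library, and its basis is not given in the sources used here. The factors were 0.936 (bam), 0.8583 (bgcn), 0.7104 (can), 1.2942 (sa) and 1.3606 (y w). These tables give no strands, so the planned comparison of antisense shares between stages was not made.

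For the aub and ago3 libraries, the authors deposited counts per transposon over all read lengths of 15 to 44 nt, length tables marked as normalised with rfam, and a combined table of normalised signal for 86 elements. Values of the combined table were whole multiples of 1 step per library for all 86 elements (tolerance 0.001 reads), so reads were worked back as 8434 (aub mutant), 83953 (aub heterozygote), 33018 (ago3 mutant) and 102700 (ago3 heterozygote). These totals lie below the totals of 23 to 29 nt reads, and the read lengths counted in that table are not given in the sources used here. Tables over all lengths were dominated by 15 to 17 nt reads, which made up 97.0% of sense reads in the aub mutant, 91.2% in the aub heterozygote, 82.5% in the ago3 mutant and 49.7% in the ago3 heterozygote. Comparisons per element therefore used the combined table. Antisense reads were taken as reads of both strands minus sense reads, from columns that name their library, and 4 antisense columns that name no sample were not used. The factor of the length table and that of the transposon lines differ, at 1.0479 against 1.00454 in the aub heterozygote and 1.00454 against 1.0479 in the ago3 mutant.

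Cluster coordinates are given as the deposited tables give them. Of the 99 clusters, 61 lie on arms such as 2LHet and U that are absent from the BDGP6 annotation and belong to Release 5 naming. No build is stated, so no gene annotation was set against them, and the names 42AB, 38C, 20A and flamenco come from textbook Release 5 locations.

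Stage comparisons used spermatogonia (bam, bgcn) and spermatocyte (can, sa) libraries with edgeR 4.0.16 (R 4.3.3), TMM scaling, the quasi-likelihood test (two-sided) and Benjamini-Hochberg adjustment, at a threshold of 0.05. Features with a count of at least 10 in at least 2 of the 4 libraries were tested, which kept 114 of 117 transposons and 99 of 99 clusters. Standard errors are the log2 fold change over the root of the F statistic. The biological coefficient of variation was 0.577 for transposons and 0.474 for clusters. The libraries of a group differed by far more than sampling noise, with a median absolute log2 ratio of shares per element of 0.67 between bam and bgcn and 0.79 between can and sa, so none was a duplicate. Lists of elements with at least 3 tested members were tested with camera in limma 3.58.1 on voom values. List names were matched without regard to case, hyphens and spaces. The ribosomal DNA list matched 2 elements and is given as values, and the Stellate and AT-chX lists matched none. On simulated counts with the real means, library sizes and dispersions and 20 changed features, the transposon test recovered 6.8% of 4-fold and 84.0% of 16-fold changes, with 0.15 and 0.55 false calls per run over 20 runs. The cluster test recovered 30.8% and 91.8%, with 0.65 and 0.80 false calls per run.

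Mutants were compared with their heterozygotes as ratios of shares of the 86 elements' reads, with a 95% exact binomial interval, and as ratios of the authors' normalised values, called levels. Elements with at least 100 reads in the 2 libraries together and a ratio of at least 2 or at most 0.5 were counted. A count of 0 was set to 3 reads for ratios, which in the counted elements applied to transib2 in the aub mutant alone, so its ratio is a floor value and not a measurement. List medians were set against 10000 random lists of the same size matched on abundance. The y w comparison used the share of each feature and its position in the range of the 4 stage libraries.

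Groups, tests, lists, alternatives and the rule for named elements were fixed before the data were examined. For the stages the rule took the 10 largest changes in each direction among features past the threshold whose groups did not overlap, the 5 most abundant in each group, and the telomeric elements and named clusters. For the mutants it took the 8 largest and 8 smallest share ratios, the 5 most abundant targets of the heterozygote and the telomeric elements, given a count of at least 10 in 1 library. Alternatives were DESeq2 1.42.0, other scalings, other count minimums, y w as a group or control, another heterozygote as control, a 4-fold rule, fry and each stage library left out in turn with the tested features kept. Scaling by the authors' factors, dropping the 5 most abundant features, reads of all lengths, Dsim-ninja in the BEL/Pao list, and other factors for the loss of 23 to 29 nt reads, for list medians and for the difference between the mutants were added after seeing the data. The element that the tables name 1360 is called by its synonym hoppel, and the gypsy-family element that the tables name 17.6 is described as the one with a numeric name. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.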

Results

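Small RNAs from Drosophila melanogaster testes were profiled to ask how PIWI-interacting RNAs (piRNAs), the 23 to 29 nt RNAs that guide Piwi proteins to transposon transcripts, differ between stages of male germline development and how they depend on the Piwi proteins Aub and Ago3. The spermatogonia group held 2 libraries from testes in which germ cells keep dividing as spermatogonia, 1 from bam mutants and 1 from bgcn mutants. The spermatocyte group held 2 libraries from can and sa mutants, meiotic-arrest genotypes whose germ cells stop as primary spermatocytes, with the apical tips cut off to remove mitotic cells. Single whole-testis libraries came from y w flies, from ago3 (t2/t3) and aub (N11/HN2) mutants, and from the ago3/TM6 and aub/CyO heterozygotes. Transposon-mapping reads numbered 438755 (bam), 580459 (bgcn), 519588 (can), 262757 (sa) and 356879 (y w) over 117 elements. Cluster-mapping reads numbered 20920, 32654, 21594, 11636 and 18371 in the same order over 99 piRNA clusters, the genomic source loci of piRNAs. Reads of 23 to 29 nt numbered 97747 in the aub heterozygote, 9437 in the aub mutant, 115785 in the ago3 heterozygote and 37932 in the ago3 mutant. The 2 libraries of a stage group are different mutants, so p-values measured the spread between those genotypes. Stage, mutant stock and the cutting of apical tips differ together between the groups. For every transposon and cluster below, a difference between stage groups cannot be assigned to 1 of these. Intervals on single libraries are 95% exact binomial intervals and cover counting error only.

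Between stages, small RNA reads mapping to a small set of retrotransposons were far more abundant in spermatocyte testes. The read lengths counted for these libraries are not given, so how many of these reads were piRNAs is not known. Relative to the typical element, Dsim-ninja, a BEL-type long terminal repeat (LTR) retrotransposon, went from 7596 ± 4869 to 92610 ± 44080 TMM-scaled rpm, reads relative to library size (SD, n = 2 each), a log2 fold change of 3.61 (SE 0.60). The related aurora-element rose by 3.45 on the log2 scale (SE 0.62), the gypsy-family element opus by 2.64 (SE 0.57) and the LINE-like element baggins by 2.61 (SE 0.57). The adjusted p-values of these 4 elements in edgeR's quasi-likelihood test were 7.03e-07, 4.76e-06, 2.03e-04 and 2.03e-04, and all 4 calls held when any of the 4 libraries was left out. In the opposite direction, Bari1, a Tc1-type DNA transposon, went from 18270 ± 12570 to 2381 ± 1596 rpm (SD, n = 2 each) with a log2 fold change of -2.94 (SE 0.70, edgeR adjusted p = 8.82e-04). HMS-Beagle, a gypsy-family element, had a log2 fold change of -2.29 (SE 0.67, edgeR adjusted p = 0.0129).

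In all, 12 of the 114 tested elements passed an adjusted p of 0.05, 10 higher and 2 lower in spermatocyte testes. The other higher elements were R1A1-element, which inserts into ribosomal DNA (2.19), diver2 (1.97), jockey (3.0), Tirant (3.67), the DNA transposon hoppel (1.53) and the foldback element FB (3.54). Each value is a log2 fold change with an edgeR adjusted p between 4.90e-03 and 0.0493. Tirant and FB had small shares, at 0.00241 to 0.0411% and 0.00999 to 0.156% of transposon-mapping reads across the 4 stage libraries. The element hoppel, sequences of which occur in the Suppressor of Stellate repeats, had the highest mean share in both groups, with 6.63 ± 1.81% of transposon-mapping reads in spermatogonia and 12.9 ± 6.52% in spermatocyte testes (SD, n = 2 each). The other abundant targets of the spermatogonia libraries did not pass the test: Doc had a log2 fold change of -0.03, roo of 0.45, copia of 0.37 and mdg3 of -0.80. The 5 largest targets together held 23.8% of reads in spermatogonia and 40.0% in spermatocyte testes. Dsim-ninja and aurora-element are related in sequence, as are members of the TART group, so reads shared between them leave their single values uncertain. The handling of reads that map to several elements is not given, so the calls of Dsim-ninja and aurora-element may rest in part on the same reads.

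**Figure D1:**
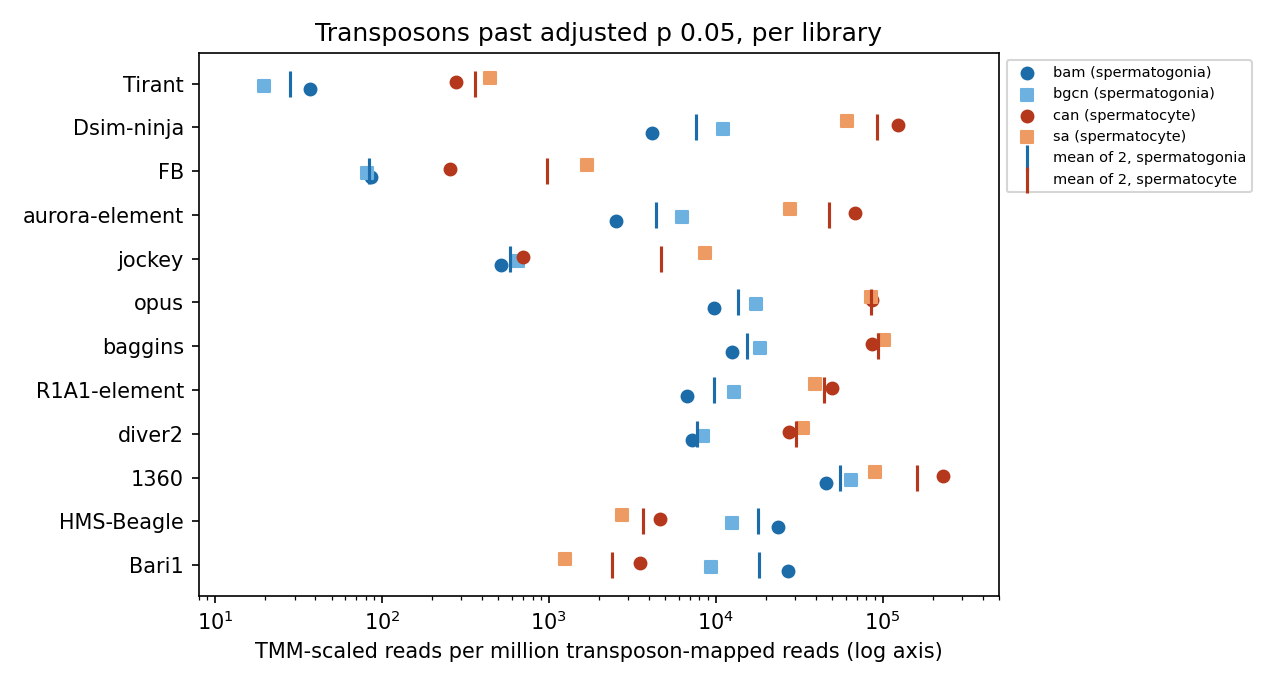
TMM-scaled rpm of transposon-mapped reads (log axis) for the 12 elements past an adjusted p of 0.05, with 1 point per library and a bar at the mean of each group's 2 libraries; hoppel stands under its numeric name. For jockey and FB the sa library lies far above can, whereas for opus and baggins both spermatocyte libraries lie close together and above both spermatogonia libraries.

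Several of these calls were lost when 1 library was left out. Without bam, 5 elements passed, and R1A1-element (edgeR adjusted p = 0.116), Bari1 (0.349), HMS-Beagle (0.349) and diver2 (0.160) were lost together with jockey (0.334), Tirant (0.187) and FB (0.334). Their log2 fold changes without bam were 1.80, -1.98, -1.77, 1.87, 2.84, 4.17 and 3.57 in that order. Without sa, 7 passed, with Bari1 at 0.158, HMS-Beagle at 0.302, diver2 at 0.0593, Tirant at 0.0555, FB at 0.414 and jockey at 0.867, and log2 fold changes of -2.09, -1.67, 2.12, 3.58, 1.91 and 0.56. Without bgcn, diver2 (0.0527), jockey (0.279), Tirant (0.393) and FB (0.393) were lost at log2 fold changes of 2.09, 3.18, 3.28 and 3.51. Without can only hoppel was lost (0.671, log2 fold change 0.72). The log2 fold change of Dsim-ninja ranged from 3.03 without can to 4.48 without bgcn, and that of aurora-element from 2.68 without can to 4.25 without sa.

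Direction counts depended on the scaling. The median log2 fold change of all elements was -0.05 after TMM scaling, -0.55 with library totals and -0.88 with the authors' own factor per library. Library totals gave 4 higher and 2 lower elements, DESeq2 gave 11 higher and 6 lower, and the authors' factors gave 2 higher and 8 lower. Those 10 calls became 0 without bam, 6 without bgcn, 1 without can and 0 without sa. With the authors' factors Dsim-ninja (2.63, edgeR adjusted p = 3.23e-03), aurora-element (2.48, 0.0167), Bari1 (-3.76, 6.95e-04) and HMS-Beagle (-3.13, 3.23e-03) still passed, whereas opus (1.72, 0.0543) and baggins (1.71, 0.0539) did not, and roo (-0.43) and copia (-0.53) took the opposite sign. In 55 of the 114 elements the groups did not overlap (48.2%, against 33.3% by chance with 2 libraries against 2).

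By family, gypsy-type LTR retrotransposons held 44.7% (bam) and 43.6% (bgcn) of transposon-mapping reads in spermatogonia and 24.5% (can) and 35.8% (sa) in spermatocyte testes. Of the 44 gypsy-family elements tested, 2 rose (opus, Tirant), 1 fell (HMS-Beagle) and 41 did not pass. Adjusted over the list alone, 1 rose and 1 fell. In the BEL/Pao family, 2 of 7 elements rose (aurora-element, diver2), also when adjusted over the list alone. Dsim-ninja, whose name the list did not match, is not among these 7. Among the 27 LINE-like elements 2 rose, baggins and jockey, also when adjusted over the list alone. Among the 14 DNA transposons hoppel and FB rose and Bari1 fell, also when adjusted over the list alone. None of the 3 copia-family elements, the 5 telomeric elements or the 10 gypsy-type elements typical of somatic gonadal cells passed, over all elements or adjusted over the list alone. The somatic-type list, which doubles as a marker of somatic cells, is a subset of the gypsy family and held 8.03% (bam), 8.54% (bgcn), 4.25% (can) and 6.58% (sa) of reads. With the authors' factors 0 gypsy-family elements rose and 3 fell, and the counts were 1 and 0 for BEL/Pao, 0 and 2 for LINE-like elements, 0 and 2 for DNA transposons and 0 and 1 for the somatic-type list. The telomeric retrotransposons protect chromosome ends. Their log2 fold changes were 0.20 for TART-A, 1.11 for TART-B, 0.88 for TART-C, -0.54 for HeT-A and -0.43 for TAHRE. Their share was 0.417% in bam against 2.03% in bgcn, with can (1.33%) and sa (0.876%) in between.

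No list passed as a whole. With limma's camera at a preset correlation of 0.01, 0 of 7 lists passed an adjusted p of 0.05 and 0 had an unadjusted p under 0.05. With Dsim-ninja added to BEL/Pao after its value was seen, 0 lists passed, with an adjusted p of 0.0661 for that list (0.787 with an estimated correlation). In the lists as fixed, the lowest adjusted p was 0.501, for the gypsy family (direction down) and for BEL/Pao (direction up). With an estimated correlation the lowest adjusted p was 0.923, and fry's lowest was 0.789. The mixed test of fry asks whether members change in either direction. Its unadjusted p-values were 0.0301 for the gypsy family, 0.0399 for BEL/Pao and 0.0112 for LINE-like elements. For the other lists they ran from 0.0521 to 0.538. These mixed p-values were not adjusted over the 7 lists, so none counts as a list that passed. Median, mean and test differed in sign for 5 lists. The medians were 0.01 for the somatic-type list, 0.37 for the copia family, -0.18 for BEL/Pao, -0.05 for LINE-like elements and 0.09 for DNA transposons. Their means were -0.19, 0.01, 0.49, 0.17 and 0.13, and camera gave the directions down, down, up, up and down.

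Among piRNA clusters, 1 locus passed the edgeR test. The cluster on the unplaced arm U from 8795936 to 8797237 had 4 (bam) and 3 (bgcn) reads in spermatogonia against 442 (can) and 603 (sa) in spermatocyte testes and 1016 in y w. Its share of cluster-mapping reads was 0.0142 ± 0.00702% and 3.62 ± 2.22% (SD, n = 2 each), with a log2 fold change of 8.97 (SE 1.07, edgeR adjusted p = 7.66e-03). A second U cluster, from 3113117 to 3137249, took 1.82 ± 1.03% and 10.8 ± 3.76% of reads but did not pass (log2 fold change 3.28, edgeR adjusted p = 0.145).

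The clusters with textbook names did not pass the test. Their positions in the tables match the Release 5 locations of those clusters. The flamenco cluster, a source of piRNAs in ovarian somatic cells, on X from 21505666 to 21684449, held 12.6 ± 1.01% and 13.2 ± 6.44% of reads (log2 fold change 0.95). The 42AB cluster, a dual-strand germline source in ovaries, on 2R from 2144349 to 2386719, held 10.6 ± 2.93% and 6.28 ± 1.40% (0.06). The 20A cluster on X from 21392175 to 21431907 held 5.06 ± 0.360% and 7.65 ± 0.105% (1.45). At 38C on 2L, the interval from 20104660 to 20118503 held 15.5 ± 8.44% and 13.0 ± 7.16% (0.51), and that from 20148259 to 20227581 held 13.6 ± 0.142% and 12.4 ± 5.49% (0.73). Each pair of percentages gives spermatogonia first (SD, n = 2 each), and each bracketed value is a log2 fold change after TMM scaling. With the authors' factors all 5 had negative values, from -1.45 (42AB) to -0.06 (20A), and none passed.

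**Figure D2:**
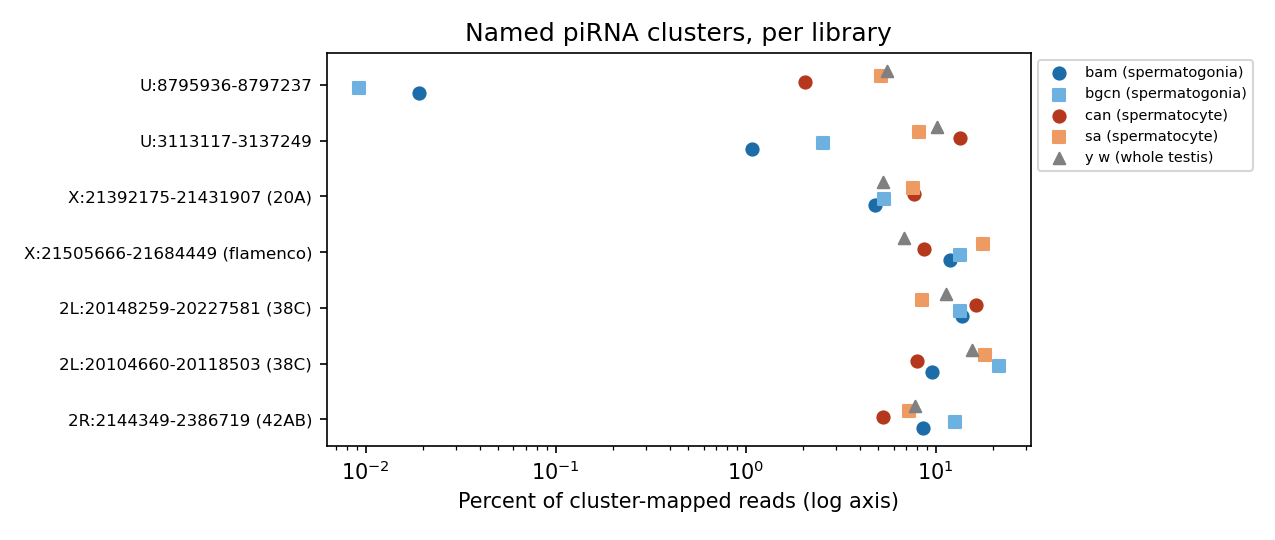
Percent of cluster-mapping reads (log axis) in each stage library and in y w for the 7 named clusters, with textbook names in brackets. The U cluster from 8795936 to 8797237 lies below 0.02% in both spermatogonia libraries and above 2% in the other 3.

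Of the 99 clusters, 1 passed in edgeR, higher in spermatocyte testes. At an unadjusted p under 0.05 there were 15 higher and 9 lower. DESeq2 called 13 higher and 4 lower, library totals 4 higher and 9 lower, and the authors' factors 3 higher and 48 lower. The median log2 fold change of all clusters was -0.11 after TMM scaling, -0.93 with library totals and -1.58 with the authors' factors. The TMM factors were uneven, from 0.686 (sa) to 1.84 (bam). Without bam the U cluster had an edgeR adjusted p of 0.226 at a log2 fold change of 9.07 (7.96 without sa, 9.54 without can) and no cluster passed, and 2, 9 and 3 passed without bgcn, can and sa. The 51 calls with the authors' factors fell to 24 without bam, 40 without bgcn, and 0 without can and 0 without sa. In 59 of the 99 clusters the groups did not overlap (59.6%, against 33.3% by chance).

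The y w testis, which holds all stages, was set against the 4 stage libraries. In y w, opus took 8.23% of transposon-mapping reads (8.14 to 8.32), above its highest stage share of 7.84%, and roo 3.27% (3.21 to 3.33), below its lowest of 3.88%. Doc took 2.79% (2.74 to 2.85) against a lowest stage share of 3.36%. The flamenco cluster held 6.77% of cluster-mapping reads (6.41 to 7.14) against a lowest stage share of 8.65%. After TMM scaling roo, Doc, flamenco and the U cluster from 8795936 (5.53% by share, above its highest stage share of 5.18%) lay within the range of the stage libraries, and opus stayed above it, but copia and mdg3, within the range by share, lay above and below it. Altogether 92 of 114 elements and 78 of 99 clusters lay within that range by share (89 and 70 after TMM scaling), where 60.0% would if all 5 libraries were alike. The element farthest outside was gypsy7, named after its value was seen, at 0.0294% (0.0241 to 0.0356) against a highest stage share of 0.0057%. Across elements, which are not independent replicates, log2 shares in y w correlated with those in can at r = 0.95, in bgcn at 0.92, in sa at 0.91 and in bam at 0.90. Across clusters the values were 0.90 (can), 0.87 (sa), 0.75 (bgcn) and 0.62 (bam).

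Transposon-mapping piRNAs were less abundant in both Piwi mutants than in their heterozygotes, and the strands differed. Each genotype had 1 library, so differences have no replicate check and no test was made. The expression of aub and ago3 themselves was not analysed here, so the genotypes rest on the labels. On the authors' scale, marked in the tables as normalised with rfam, reads of 23 to 29 nt were 10.4-fold lower in the aub mutant than in its heterozygote (10.2 to 10.7) and 3.04-fold lower in the ago3 mutant (3.0 to 3.07). In the aub mutant sense reads were 31.6-fold lower (30.1 to 33.2) and antisense reads 6.17-fold lower (6.03 to 6.32). In the ago3 mutant the order was the opposite, with sense reads 2.34-fold lower (2.30 to 2.38) and antisense reads 3.93-fold lower (3.87 to 4.0). The antisense share was 49.3% (48.9 to 49.6) in the aub heterozygote and 83.2% (82.5 to 84.0) in the aub mutant. It was 56.8% (56.5 to 57.1) in the ago3 heterozygote and 43.9% (43.4 to 44.4) in the ago3 mutant. The factor sets in the files differ, and the normalised totals over the 86 elements of the combined table gave an 8.14-fold loss in the aub mutant and a 4.74-fold loss in the ago3 mutant.

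Sense piRNAs of 26 nt took a smaller share in both mutants. They made up 37.1% (36.7 to 37.6) of sense reads of 23 to 29 nt in the aub heterozygote and 17.8% (15.9 to 19.7) in the mutant. The corresponding shares were 42.1% (41.7 to 42.5) and 20.6% (20 to 21.1) in the ago3 pair. Antisense reads had their mode at 25 nt in both heterozygotes and the ago3 mutant and at 26 nt in the aub mutant. Sense reads of 21 nt, the length of small interfering RNAs, were close to their heterozygote level in the aub mutant, at a ratio of 0.976 (0.941 to 1.01), and at 0.804 (0.764 to 0.845) in the ago3 mutant.

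**Figure D3:**
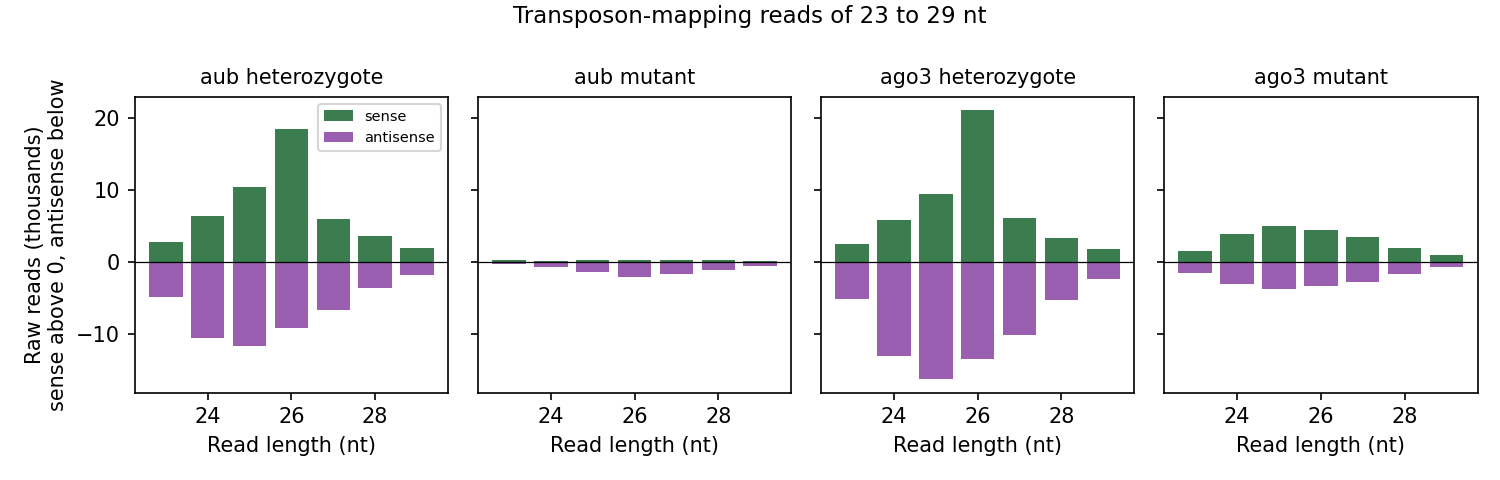
Raw transposon-mapping reads (axis in units of 1000 reads) by read length from 23 to 29 nt, sense above 0 and antisense below, in the aub and ago3 heterozygotes and mutants (1 library each). The sense peak at 26 nt seen in both heterozygotes (18421 and 21065 reads) is lower in the aub mutant (281 reads) and the ago3 mutant (4380 reads).

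In the aub mutant, reads mapping to most transposons were far below the heterozygote level while those mapping to many gypsy-family elements were near it. Dsim-ninja had 4509 reads in the heterozygote and 6 in the mutant, a normalised level of 0.00163 of the heterozygote (0.000597 to 0.00354), and hoppel had 13886 and 66 reads, a level of 0.00581 (0.00449 to 0.00740). The levels of aurora-element (0.00478), diver2 (0.00603), X-element (0.00612), pogo (0.00557, interval 0.000672 to 0.0202 from 2 reads), hopper2 (0.00493, interval 0.000124 to 0.0277 from 1 read) and invader6 (0.00356, interval 0.000734 to 0.0104 from 3 reads) were of the same order. Among the other abundant targets, opus was at 0.0662, copia at 0.0554 and baggins at 0.0202 of the heterozygote level. In contrast, ZAM was at 1.31 (0.892 to 1.93), Tabor at 1.12 (0.933 to 1.34), gtwin at 1.10 (0.916 to 1.32), rover at 1.07, gypsy10 and gypsy6 at 1.02 each, gypsy2 at 0.997 and gypsy3 at 0.959. The telomeric HeT-A was at 0.752 (0.469 to 1.19, 32 reads), TART-A at 0.0905 (0.0544 to 0.143), TART-B at 0.0509 (0.00600 to 0.194, 2 reads) and TART-C at 0.0249 (0.000619 to 0.146, 1 read).

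As shares of transposon reads, the planned measure, 21 of the 72 elements with at least 100 reads were at least 2-fold higher in the aub mutant and 35 at least 2-fold lower. On the authors' normalised values 0 were higher and 54 lower, with raw reads 0 were higher and 56 lower, and with median-of-ratios scaling 26 were higher and 21 lower. Among elements with reads in both libraries, share ratios ran from 0.0132 (Dsim-ninja) to 10.7 (ZAM). The DNA transposon transib2, named after its value was seen, had 591 reads in the heterozygote and 0 in the mutant, which gives a share ratio of 0.0505 and a level of 0.0062 at a floor of 3 reads, with exact upper limits of 0.0623 and 0.00765. All 9 somatic-type elements with enough reads were at least 2-fold higher in share but none in level, where 8 were within 2-fold and 1 lower. Their median level ratio was 0.762, at percentile 97.5 of 10000 random lists matched on abundance. The gypsy family (35 elements) had a median level ratio of 0.6 (percentile 100) and, with all 37 matched members, took 81.5% of reads in the mutant against 35.2% in the heterozygote, with a summed level of 0.285. In that family 18 elements were within 2-fold of the heterozygote level and 17 were at least 2-fold lower. The DNA transposons (7 elements) had a median level ratio of 0.00581 with the 0 reads of transib2 as 0 and 0.0062 with them at the 3-read floor (percentile 0.1). The BEL/Pao, LINE-like and copia lists had median level ratios of 0.0452, 0.0453 and 0.0554 (percentiles 28.9, 38.1 and 33.8), and 1 telomeric element had enough reads.

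In the ago3 mutant, median levels were above those of the aub mutant for the copia, BEL/Pao, LINE-like and DNA transposon lists, with the lowest median for DNA transposons. Medians for the gypsy family were 0.303 in the ago3 and 0.6 in the aub mutant on the normalised values of the combined table. They were 0.462 and 0.491 with raw reads, and 0.464 and 0.488 with the factors marked as rfam. The gap between the mutants in this family therefore rests on the combined table's factors. The LINE-like element Ivk had 172 reads in the heterozygote and 3 in the mutant, a level of 0.0114 of the heterozygote (0.00234 to 0.0340). The DNA transposons pogo (0.0311), hopper2 (0.0425), transib2 (0.0513) and Bari1 (0.0540) followed, with the LTR elements diver (0.0583), accord (0.0604) and 1 gypsy-family element with a numeric name (0.0578). The most abundant target, hoppel, had 19698 and 1827 reads, a level of 0.0608 (0.0579 to 0.0638). The other abundant targets were at 0.147 (roo), 0.164 (baggins), 0.321 (opus) and 0.469 (copia). The elements with the highest ratios were 3S18 at 0.699, springer at 0.651, HeT-A at 0.644, Tabor at 0.607, gypsy2 at 0.552, gypsy5 at 0.519, gypsy3 at 0.502 and Max-element at 0.490. The TART elements were at 0.266 (TART-A), 0.196 (TART-B) and 0.0789 (TART-C).

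As shares, 12 of 79 elements were at least 2-fold higher and 12 at least 2-fold lower in the ago3 mutant. On the authors' normalised values 0 were higher and 72 lower, with raw reads 0 and 58, and with median-of-ratios scaling 8 and 15. The DNA transposons (7 elements) had a median level ratio of 0.054 (percentile 0.0 of 10000 random lists) and, with all 9 matched members, held 23% of reads in the heterozygote and 6.74% in the mutant. The gypsy family had 0.303 (36 elements, percentile 99.6) and the somatic-type list 0.379 (9 elements, percentile 99.3), with 7 of the 9 at least 2-fold lower and 2 within 2-fold. The copia, BEL/Pao, LINE-like and telomeric lists had 0.348, 0.147, 0.216 and 0.228 (percentiles 89.8, 11.1, 33.4 and 58.9). With raw reads the medians of these 7 lists were 0.0824 (DNA transposons), 0.462 (gypsy family), 0.577 (somatic-type), 0.53 (copia), 0.224 (BEL/Pao), 0.329 (LINE-like) and 0.348 (telomeric). The somatic-type median in the aub mutant was 0.623 with raw reads.

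**Figure D4:**
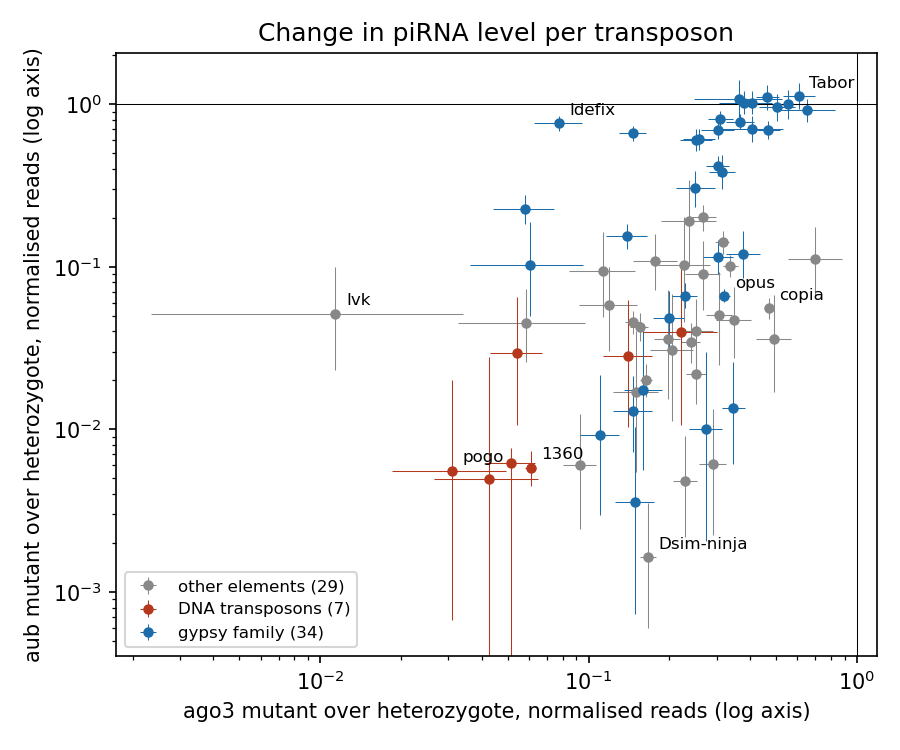
Normalised reads in the mutant over its heterozygote for ago3 (horizontal, log axis) and aub (vertical, log axis), 1 point per element with at least 100 reads in each pair, with 95% exact binomial counting intervals and transib2, with 0 aub mutant reads, drawn at the 3-read floor (0.0062). Tabor of the gypsy family lies high on both axes (0.607 and 1.12), the DNA transposon hoppel, under its numeric name, lies low on both (0.0608 and 0.00581), and Dsim-ninja lies lowest for aub (0.00163).

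The share ratios of the 2 mutants differed for most elements. Of 70 elements with enough reads in both pairs, the log2 share ratios differed by at least 1 in 54, with 23 higher in the aub mutant and 31 lower. With median-of-ratios scaling the split was 30 and 19, on the authors' normalised values 13 and 40, and with raw reads 4 and 46. Each difference rests on 4 single libraries, and the heterozygotes also differed from each other. G-element took 1.41% of reads in the ago3 and 0.324% in the aub heterozygote, and springer 0.139% and 0.419%. These counts therefore hold differences between libraries and control genotypes as well as any effect of the mutations. The log2 share ratio of Dsim-ninja was -0.34 in the ago3 mutant and -6.24 in the aub mutant, and that of aurora-element was 0.12 and -4.68. Idefix, named after its values were seen, had -1.44 and 2.63. Across elements, which are not independent replicates, the ratios correlated at r = 0.48 (0.41 to 0.51 from counting error, Spearman rho 0.56). With y w as the control of both, r was 0.54 with a covariance of 2.17, against a simulated r of 0.47 and covariance of 0.82 when neither mutant differed from y w. The y w library was not split, so its own counting and genotype differences enter both ratios. Differences in how y w and mutant reads were counted, whose read lengths are not given, enter both ratios too. The simulation drew counts with the spread of the stage libraries and held no such differences, so it cannot show whether the mutants share an effect.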

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

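Every test in this part was chosen after its result was seen, except the comparison of gypsy-family shares with reads of all lengths.

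The antisense share of 23 to 29 nt reads moved in opposite directions, by 33.9 percentage points in the aub mutant and by -12.9 in the ago3 mutant. Elements whose share at least doubled in one mutant and at least halved in the other were Idefix, with a log2 share ratio 4.07 higher in the aub than in the ago3 mutant, copia (-2.31) and Max-element (-2.99). These differences were not tested, since each genotype had 1 library. Outside the piRNA lengths, sense reads of 15 to 17 nt were at 2.44 times the heterozygote level in the ago3 mutant (2.41 to 2.46) and at 0.818 in the aub mutant (0.815 to 0.82). The heterozygotes differed far more from each other, with 58728 (ago3) and 729846 (aub) such raw reads. These ratios therefore cannot be told apart from differences between libraries.

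In the aub mutant 18 of 35 gypsy-family elements were within 2-fold of the heterozygote level and 17 were lower (16 within 2-fold with raw reads), with a summed level of 0.285 for the family. The family's median level ratio of 0.6 was 15.1 times that of the other 37 elements (0.0397). Scaling moves every element alike, so it cannot by itself give this gap. How near the family lay to the heterozygote level does depend on the scaling, and this comparison does not address it. That all of the family's reads were breakdown fragments with the strand ratio of all lengths is argued against, since at most 66.8% of 23 to 29 nt reads would then be antisense, against 83.2% seen (82.5 to 84.0), if the family's reads had those lengths. Fragments may still be a part of the family's reads (up to 50.4% at that strand ratio) or have another strand ratio. Such fragments cannot be told apart from kept piRNAs. The family's share was 1.44 times its share of reads of all lengths, where at most 1.76 was possible. That value lay inside the limit set beforehand as fitting breakdown fragments, and the strand comparison was added later. Across the 18 elements mutant reads had a Spearman rho of 0.10 with reads of all lengths, which were mostly of 15 to 17 nt. Their rho with heterozygote reads was 0.93, but the 18 were picked for levels within 2-fold of the heterozygote. A high value was thus built in and does not weigh against fragments. A candidate explanation that stays open is that piRNAs of somatic cells do not need Aub. By share the somatic-type list stood at percentile 99.3 of random lists in the ago3 mutant too. The gypsy family, which contains the list, stood at 99.6, so this percentile does not set somatic-type elements apart from the family. By level 7 of the list's 9 elements were at least 2-fold lower in the ago3 mutant (5 of 9 within 2-fold with raw reads). In the aub mutant 8 of the 9 listed elements with enough reads were within 2-fold of the heterozygote level. So were 10 of 63 elements outside the list, among them gypsy2, gypsy3 and rover.

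The U cluster from 8795936 to 8797237 had 4 and 3 reads in the spermatogonia libraries. Library depth is argued against, since its lowest spermatocyte share would give 428 reads in bam and 668 in bgcn. A strain variant of the locus cannot be told apart from the stage with these tables, because the 7 reads in both libraries may come from the locus or from a related repeat and each stage group holds its own mutant stocks. The stage difference named by the design stays open and was not tested apart from genotype.

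With the authors' factors the typical transposon and cluster were lower in spermatocyte testes. A single library is argued against as the cause, since the medians of all 4 pairs of libraries were between -1.21 and -0.67 for transposons and between -1.79 and -1.32 for clusters, beyond the largest within-group medians of 0.47 and 0.29. Whether the authors' factors alone gave this shift cannot be told apart from a lower level per cell. A wrong factor would move both tables alike, and the cluster median lay lower than the transposon median by a mean of -0.64, but within groups that difference reached 0.69. Stage, genotype and the cutting of apical tips stay open.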

How the results depend on the processing

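The tests with the authors' factors between stages, without abundant features, with reads of all lengths, with Dsim-ninja in the BEL/Pao list and with other factors for the loss of 23 to 29 nt reads, list medians and the difference between the mutants were chosen after the result was seen. Where no cause is named below, the cause was not tested. Comparisons by strand and of the antisense share between stages were not run, since the tables used give no strands per element, nor were pseudocounts, since counts were used. On simulated counts 6.8% of 4-fold changes were recovered for transposons and 30.8% for clusters, although transposons had more reads, and depth was not varied. Depth limits elements with few mutant reads, such as hopper2 with 1. Removing 1 library leaves a lone sample assumed to vary like the other group.

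Transposon calls between stages (12) went to 6 with library totals, and ranged from 5 to 12 when a library was left out. With the authors' factors (10 calls) that range was 0 to 6. Cluster calls (1) went to 17 with DESeq2, 13 with library totals, 12 with a count of at least 100, 15 with y w as a group and 51 with the authors' factors. They ranged from 0 to 9 when a library was left out, and from 0 to 40 with the authors' factors. No list passed with an estimated correlation, library totals, fry, the authors' factors, Dsim-ninja added to BEL/Pao or any library left out. Settings that keep every stage library gave 483 values for single elements, clusters or list medians. Of these, 230 were the same, 56 turned, 175 moved by more than their error, 19 lost and 3 gained a call. For stage features the same meant direction and side of the threshold, and for mutant elements a value inside its counting interval. For single mutant elements a turned sign was counted only past the size rule.

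None of the following stage elements passed in the main test. Their log2 fold changes took the other sign with library totals for roo (-0.08), copia (-0.14), TART-A (-0.35), 42AB (-0.75) and the 38C intervals (-0.25 for the first, -0.13 for the second). With the authors' factors the values were -0.43 (roo), -0.53 (copia), -0.18 (TART-C), -0.77 (TART-A), -0.06 (20A), -0.60 (flamenco), -1.45 (42AB), -1 (first 38C interval) and -0.77 (second). A count of at least 100 gave -0.57 (42AB) and -0.10 (first 38C interval), and y w as a group -0.07 (42AB). Doc was at 0.07 with DESeq2 and 0.07 without the 5 most abundant elements. With a library left out, values ranged from -0.09 to 5.49 (TART-C), -0.40 to 1.23 (TART-A), -1.26 to 0.98 (HeT-A), -1.16 to 0.98 (TAHRE), -0.45 to 0.56 (Doc), -0.38 to 1.82 (first 38C interval) and -0.49 to 0.92 (42AB).

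In the ago3 mutant, 24 elements passed the size rule. This became 58 with raw reads and 72 with the authors' values, both keeping the overall loss that shares remove, 8 with at least 1000 reads and 4 with a 4-fold rule, which admit fewer elements, 37 with y w as control and 47 with reads of all lengths. In the aub mutant, 56 became 18 with at least 1000 reads and 4 with reads of all lengths. The fold loss of 23 to 29 nt reads was 2.91 (ago3) and 10 (aub) with the factor of the transposon lines, and 4.74 and 8.14 over the 86 elements. With reads of all lengths the antisense share differed by -2.2 points (ago3) and 0.2 points (aub).

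Log2 ratios that were positive as shares became negative with other scalings. In the ago3 mutant, raw reads gave -0.48 (copia), -0.03 (HeT-A), -0.01 (springer), -0.11 (Tabor), -0.25 (gypsy2), -0.38 (gypsy3), -0.34 (gypsy5) and -0.42 (Max-element). The authors' values gave -1.09, -0.64, -0.62, -0.72, -0.86, -0.99, -0.95 and -1.03 in that order, and -0.52 for 3S18. In the aub mutant, raw reads gave -0.13 (Tabor), -0.15 (gtwin), -0.29 (gypsy2), -0.35 (gypsy3), -0.26 (gypsy6), -0.19 (rover) and -0.26 (gypsy10), and the authors' values -0.06 (gypsy3) and 0.00 after rounding (gypsy2). Reads of all lengths turned the element with a numeric name (0.13), pogo (0.11), TART-C (0.68), diver (0.63), accord (0.51), Ivk (0.27) and copia (-0.61) in the ago3 mutant, and pogo (0.15), gypsy3 (-0.19) and rover (-0.02) in the aub mutant.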

Other observations

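The distribution of clusters over chromosome arms placed 61 of 99 on heterochromatic or unplaced arms, with 18 on 3RHet, 17 on U, 13 on 3LHet and 10 on 2RHet. A few loci supplied most reads: the 5 largest held 57.4% of cluster-mapping reads in spermatogonia and 57.1% in spermatocyte testes. Across features, the correlation of log2 shares was 0.83 for clusters and 0.91 for transposons between bam and bgcn, and 0.88 and 0.92 between can and sa. The median absolute log2 ratio of shares was 0.91 and 0.67 between bam and bgcn, and 0.58 and 0.79 between can and sa.

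The hypothesis that the transposon-mapping small RNAs enriched in spermatocyte testes depend more on Aub was tested across elements. Both its tests were chosen before their results were seen. Of the 8 elements called higher in spermatocyte testes and matched in the mutant table, 6 had an aub share ratio of at most 0.5, as did 35 of all 72 elements, and 2 had such an ago3 ratio, as did 12 of all 79. Over 72 elements the stage log2 fold change and the aub log2 share ratio had a Spearman rho of -0.16 (Pearson r -0.23, permutation p = 0.19, adjusted over the 2 relations 0.38), and without the called elements rho was 0.01. For Ago3, over 79 elements, rho was -0.02 (Pearson r 0.00, permutation p = 0.89, adjusted 0.89). A permutation p above 0.05 had been set to count against the hypothesis, but a missed threshold does not exclude a relation, so it stays open. Elements are not independent replicates.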
